A study of Mus musculus with 6 samples.

How the data were processed

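Total RNA of ileal mucosa was extracted with TRIzol, treated with deoxyribonuclease and purified on silica columns, and labelled with biotin by in vitro transcription, per the labels' protocols. RNA of 2 to 3 animals was pooled per cage and genotype before labelling, so that the 6 single-colour Affymetrix arrays held 3 wild-type and 3 Duoxa-/- pools from 3 cages. The deposited values are log2 summaries of probe sets made by the authors with RMA in the affy package, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each set on the log2 scale, which compresses differences of dim probe sets. Versions and settings are not given in the sources used here. The 6 columns had nearly but not exactly equal quartiles, medians of 6.55 to 6.60 and values between 3.13 and 15.59, with 0 missing. No raw intensities or detection calls were used here, so dim probe sets were judged by their level alone.

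The table held 45101 rows, of which 64 control probe sets were left out. Of the 45037 others, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 were unnamed; the last 2 kinds entered only the test of all probe sets. Symbols were updated through gene identifiers against the RefSeq table of assembly GRCm38.p6, where 34741 probe sets matched and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over the 6 arrays, since 9010 genes had more than 1. Coordinates entered only the test of genes near the locus.

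Differences between genotypes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05) on all 6 arrays without a cage term. All adjusted p values are from limma. Genes between cages were tested with limma's moderated F-test with genotype in the fit. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Differences are Duoxa-/- minus wild type on the log2 scale, SE and confidence intervals are from limma, and SD is over the 3 pools of a group.

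The fits, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 42 lists (20 pathways, 22 cell types) held 706 entries, 630 of them measured, 2 under an older symbol; the Paneth cell list had 9 of 20 entries measured, and some genes stand in more than 1 list. Lists with at least 4 measured members were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, then with a correlation estimated from the data and with fry, a rotation test that asks whether the genes of a list move one way on balance. With an estimated correlation and by fry, 0 lists passed (smallest adjusted p 0.909 for the called lists with the estimated correlation), while 7 passed at the preset correlation. An exact two-sided permutation test of list scores over the 20 assignments of the arrays cannot give a p under 0.1. For the 7 lists that passed at the preset correlation, the p of this test lay between 0.2 and 0.6, above that floor.

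The text names the genes of the locus, the 12 genes with the largest difference in each direction among those with the same sign in all 3 cages whose higher group mean reached the median of all probe sets (6.58), as no gene passed, up to 3 members of each list with the smallest p, and the 10 genes with the smallest p between cages. Other genes are marked as chosen after their values were seen.

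A cage is a litter per the series' design text, which pairs the pools. Deviations of the 2 pools of a cage from their group means correlated across genes with r = -0.18 in cage 1, 0.16 in cage 2 and 0.34 in cage 3. Pools of different cages gave r from -0.44 to 0.40, so these correlations do not show the pairing in the data. Because of the design, the fit with cage as a replicate block is given beside results it changes. The animals of a pool share an array, so p values of single genes measure the spread between pools. Camera at the preset correlation sets the genes of a list against the other genes, so its p values rest on the spread over genes. For proliferation its adjusted p was 7.5e-05, while the exact permutation of the arrays gave a p of 0.2.

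The genotype fits and the F-test between cages were run on simulated data with the real gene means and 200 of 18193 genes changed. Gene spreads were drawn at random from the distribution fitted to these arrays, and the noise was independent between genes and between arrays. The unblocked fit called 46.2%, 94.8% and 99.6% of genes changed 1.5-fold, 2-fold and 4-fold, and the blocked fit 0%, 89.6% and 99.6%. The F-test called 0%, 80.9% and 99.1% of genes changed by these folds in cage 3. A shift of 0.3 in the defence list, in genes simulated as independent, was called by camera in 20 of 20 simulations at the preset correlation and in 15 of 20 with an estimated one, and by fry in 19 of 20. As a sign of RNA integrity, the control probe sets for the 3' end of beta-actin read 0.44 and 0.60 above those for its 5' end in the wild-type and Duoxa-/- pools of cage 1, 0.79 and 0.48 in cage 2 and 0.42 and 0.42 in cage 3.

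The alternatives were the cage block, cyclic loess, centring on array medians, leaving out the dimmest 40% of genes, all probe sets, the mean of a gene's probe sets, leaving out probe sets marked as cross-hybridising, an intensity trend with a robust prior, array weights, other thresholds, and leaving out each array and each cage.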

Results

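Gene expression was profiled in the mucosa of the terminal ileum, the last stretch of the small intestine, of 3-month-old female 129S6 mice. Duoxa-/- mice lack the DUOX maturation factors, the proteins that the dual oxidases DUOX1 and DUOX2 need to reach the cell surface, where these enzymes release hydrogen peroxide. The comparison asked how ileal expression differs between Duoxa-/- mice and wild-type littermates that shared their cage. There were 3 wild-type and 3 Duoxa-/- samples, each a pool of RNA from 2 to 3 animals, and each of the 3 cages (1 litter each) gave 1 pool per genotype. Each pool was measured on 1 array, and the number of arrays limits the precision of all values below. The 6 arrays had medians of 6.55 to 6.60 on the log2 scale and correlated across probe sets with r of 0.994 to 0.998. The wild-type pool of cage 1 had the lowest mean correlation with the other arrays (r = 0.994 across probe sets). Its mean value of the smooth muscle genes lay 0.41 above the mean of all arrays, and its T cell genes lay at -0.37 and its interferon-stimulated genes at -0.44 relative to that mean, while the T cell genes of the wild-type pool of cage 2 lay farther from it, at 0.43.

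Duoxa2 fell in the Duoxa-/- pools. Its probe set (1422137_at) read 8.14 ± 0.81 in wild-type pools (SD, n = 3) and 5.79 ± 0.21 in Duoxa-/- pools (SD, n = 3), a log2 difference of -2.34 with a 95% confidence interval of -3.13 to -1.56, or 5.08-fold lower. The difference was -2.90 in cage 1, -2.81 in cage 2 and -1.32 in cage 3, where the wild-type pool read 7.24 against 8.81 and 8.36 in the other cages. Adjusted over the measured genes of the locus, Duoxa1, Duoxa2 and Duox1, limma gave an adjusted p of 3.6e-04. Adjusted over all 18193 genes, Duoxa2 did not pass (adjusted p = 0.760). It did pass over all genes when the wild-type pool of cage 3 was left out (adjusted p = 0.0136). Duoxa1 (1460372_at) differed by -0.15 (95% interval -0.42 to 0.12; adjusted p over the locus genes 0.349), from a level of 6.31 ± 0.09 (SD, n = 3) in wild-type pools that lies below the median of all probe sets, 6.58. Duox1 (1456877_at) was dimmer still at 4.75 ± 0.14 (SD, n = 3) and differed by 0.09 (95% interval -0.12 to 0.31; adjusted p 0.354). Duox2 was not analysed here. Whether these probe sets lie inside the deleted part of the locus is not given in the sources used here, and a probe set outside it would not check the genotype.

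**Figure D1:**
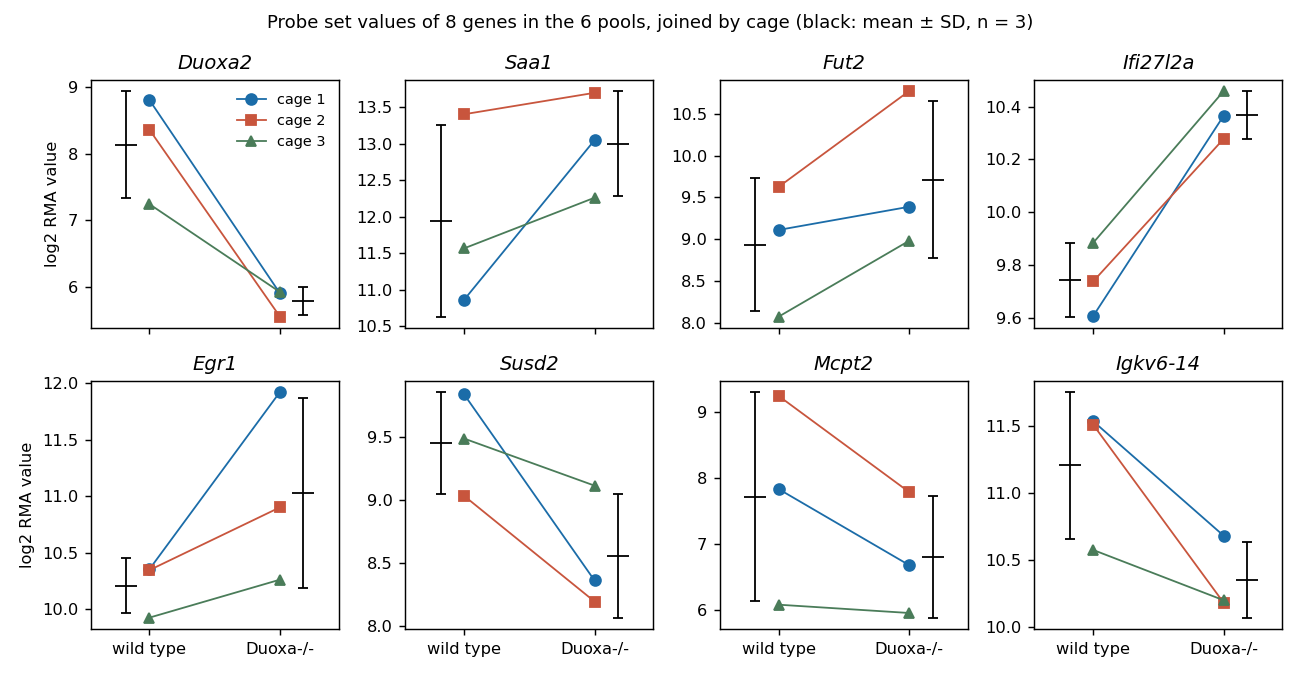
Log2 RMA values of 8 genes in the 6 pools, with the wild-type and Duoxa-/- pool of each cage joined by a line and the group mean ± SD (n = 3) in black; each panel has its own axis. Duoxa2 reads from 7.24 to 8.81 in wild-type and from 5.55 to 5.92 in Duoxa-/- pools, and Ifi27l2a is higher in the Duoxa-/- pool of every cage.

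Across the ileal transcriptome no single gene separated the genotypes after adjustment over all genes. With limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.760, while 1006 genes had an unadjusted p under 0.05 against 910 by chance. With cage as a replicate block, 0 genes passed as well and 1166 had an unadjusted p under 0.05. The differences were small: 41 genes reached 1.5-fold and 5 genes reached 2-fold, with a median standard error of 0.10 on the log2 scale. In simulated data with independent genes, whose spreads were drawn from the distribution fitted to these arrays, the fit called 46.2% of genes changed 1.5-fold. It called 94.8% of genes changed 2-fold, when 200 genes changed together, and fewer changed genes were not simulated. These shares do not hold for a gene of wide spread such as Duoxa2, 5.08-fold lower with an SD of 0.81 in wild-type pools, which did not pass.

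Among genes that were higher in the Duoxa-/- pool of all 3 cages and whose higher group mean reached 6.58, the median of all probe sets, the 12 largest differences included serum amyloid and interferon-induced genes, given here as values that did not pass the test. Plet1, a glycosylated surface protein, was higher by 1.29 (SE 0.87), a mean set mainly by cage 1 (3.03, against 0.07 and 0.76). The acute-phase serum amyloid genes Saa1 and Saa2, whose near-identical transcripts the probe sets may not separate, were higher by 1.06 (SE 0.61) and 0.68 (SE 0.47). Fut2, the fucosyltransferase that builds fucosylated surface glycans, was higher by 0.78 (SE 0.50), with 0.28, 1.15 and 0.91 in cages 1, 2 and 3. Ifi27l2a, an interferon-induced gene, was higher by 0.63 (SE 0.10), with 0.76, 0.54 and 0.58 in the 3 cages. Ifit2 (0.82) and Slfn4 (0.67), both interferon-induced, the immediate early transcription factor Egr1 (0.82), the lipopolysaccharide receptor Tlr4 (0.68), the chemokine Ccl20 (0.62), the manganese exporter Slc30a10 (0.66) and the pseudogene Bambi-ps1 (0.72) completed the 12. For Tlr4, 3 of its 4 probe sets shared this sign. The limma adjusted p of these 12 genes lay between 0.760 and 0.815.

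Among genes lower in the Duoxa-/- pool of all 3 cages, with the same limit on expression, Duoxa2 had the largest difference. The others included the immunoglobulin kappa variable segments Igkv6-20 (-1.17, SE 0.48), Igkv14-111 (-0.90, SE 0.40) and Igkv6-14 (-0.85, SE 0.26). Segments of this family are similar in sequence, so their probe sets may read several of them. Mcpt2, a protease of mucosal mast cells, was lower by a log2 difference of -0.91 (SE 0.74). Its values in wild-type pools ranged from 6.08 in cage 3 to 9.24 in cage 2. The membrane protein Susd2 (-0.90), the solute carrier family member Slc5a4a (-0.80), the sugar transporter Slc2a2 (-0.65), the leukocyte surface genes Cd99 (-0.73) and Cd7 (-0.63), Mlf2 (-0.62) and the flavin monooxygenase Fmo5 (-0.60) were also among them. Apart from Duoxa2, the adjusted p of these 11 genes lay between 0.811 and 0.819.

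The microbe-responsive epithelial defence genes had the highest median difference of the 42 gene lists fixed before the data were examined. Their median log2 difference was 0.27, with 14 of 18 measured members higher in Duoxa-/- pools and 9 of them higher in all 3 cages, against 12.5% of genes by chance if signs were independent. Over all genes, 30.1% shared 1 sign in 3 cages, against 25% by chance. The exact two-sided permutation of the arrays gave a p of 0.5 for this list. The list mean was higher by 0.30 ± 0.12 (SD over 3 cages), and the list medians were 0.21, 0.16 and 0.18 in cages 1, 2 and 3. Sprr1a, a cornified-envelope protein, was higher by 0.47 (SE 0.12), the inducible nitric oxide synthase Nos2 by 0.40 (SE 0.14) and the transglutaminase Tgm2 by 0.25 (SE 0.12). Adjustment over a list alone was not extended over the 42 lists, so some lists are expected to hold a passing member by chance. Adjusted over the list alone, 0 members passed without the block. With cage as a block, 3 passed over the list alone, Sprr1a, Nos2 and Fut2, each with an adjusted p of 0.0315, against 0.075, 0.216 and 0.407 without it. Of the members chosen after their values were seen, the C-type lectins Reg3b and Reg3g, among the brightest genes of the array at 14.6 and 14.5 in wild-type pools, differed by 0.09 (SE 0.08) and 0.11 (SE 0.10), and Lcn2, a siderophore-binding protein, by -0.05 (SE 0.16). The list passed camera, limma's competitive set test, at its preset correlation (adjusted p = 0.0011), and not with a correlation estimated from the data (adjusted p = 0.909). Leaving out the Duoxa-/- pool of cage 2 (median 0.15, adjusted p = 0.090) or the wild-type pool of cage 3 (median 0.20, adjusted p = 0.058) also ended the call. The median was 0.18 without the wild-type pool of cage 1, 0.50 without the Duoxa-/- pool of cage 3 and 0.15 without cross-hybridising probe sets, each of these still called.

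Interferon-stimulated genes had a median difference of 0.16, with 23 of 26 members higher. Rsad2 (0.45, SE 0.14), Oas2 (0.51, SE 0.17) and Oas1a (0.35, SE 0.11), which encode antiviral effectors, were higher in all 3 cages. The list medians differed between cages, at 0.59 in cage 1, -0.12 in cage 2 and 0.08 in cage 3. Camera gave an adjusted p of 2.2e-04 at the preset correlation and an adjusted p of 0.909 with an estimated correlation, and adjusted over the list alone 0 members passed. Without the wild-type pool of cage 1, which also had the lowest interferon score, the median was 0.02 and the adjusted p 0.099, and without cage 1 the median was -0.0023 (adjusted p = 0.640). The median was 0.066 without the Duoxa-/- pool of cage 1 and 0.34 without the wild-type pool of cage 2, both still called.

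Cell proliferation genes had a median difference of 0.14, with 21 of 22 members higher and 9 higher in all 3 cages. Rrm2, a subunit of ribonucleotide reductase, was higher by 0.39 (SE 0.18), the mitotic kinase Aurka by 0.25 (SE 0.11) and Birc5, a protein of the chromosomal passenger complex, by 0.22 (SE 0.11). The list medians were 0.36, 0.07 and 0.02 in cages 1, 2 and 3. The list had the smallest camera p of all lists (adjusted p = 7.5e-05), and an adjusted p of 0.909 with an estimated correlation, and adjusted over the list alone 0 members passed. Without cage 1 the list did not pass (median 0.049, adjusted p = 0.201). The median was 0.071 without the wild-type pool of cage 1, 0.26 without that of cage 2 and 0.24 without the Duoxa-/- pool of cage 3, each still called.

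Immediate early and heat shock genes had a median of 0.13, with 14 of 17 members higher, among them Egr1, Fos (0.26, SE 0.13) and the mitochondrial chaperonin Hspd1 (0.21, SE 0.09). Inflammatory cytokines and chemokines had a median of 0.09, with 20 of 26 higher, among them Il1b (0.52, SE 0.14), which encodes interleukin-1 beta, Cxcl16 (0.20, SE 0.11) and Ccl7 (0.13, SE 0.07). Both lists passed camera (adjusted p = 0.0089 and 0.027), neither did with an estimated correlation (adjusted p = 0.909 for both), and in both 0 members passed over the list alone. Leaving out dim genes ended both calls (adjusted p = 0.052 and 0.223), with 16 members left in each list and medians of 0.14 and 0.11. The immediate early call also ended without the wild-type pool of cage 2 (median 0.083, adjusted p = 0.184) or its Duoxa-/- pool (adjusted p = 0.086). Without cage 2 its median was -0.00020 (adjusted p = 0.588), and its list medians were 0.22, 0.29 and -0.03 in cages 1, 2 and 3, against 0.30, 0.04 and -0.07 for the cytokine list. The cytokine call also ended without either pool of cage 1 (median 0.041, adjusted p = 0.344 without the wild-type and median 0.055, adjusted p = 0.218 without the Duoxa-/- pool) or without the Duoxa-/- pool of cage 2 (median 0.043, adjusted p = 0.168). Its median was -0.0025 without cage 1, and 0.15 without the wild-type pool of cage 2 and 0.19 without the Duoxa-/- pool of cage 3, both of the last still called.

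**Figure D2:**
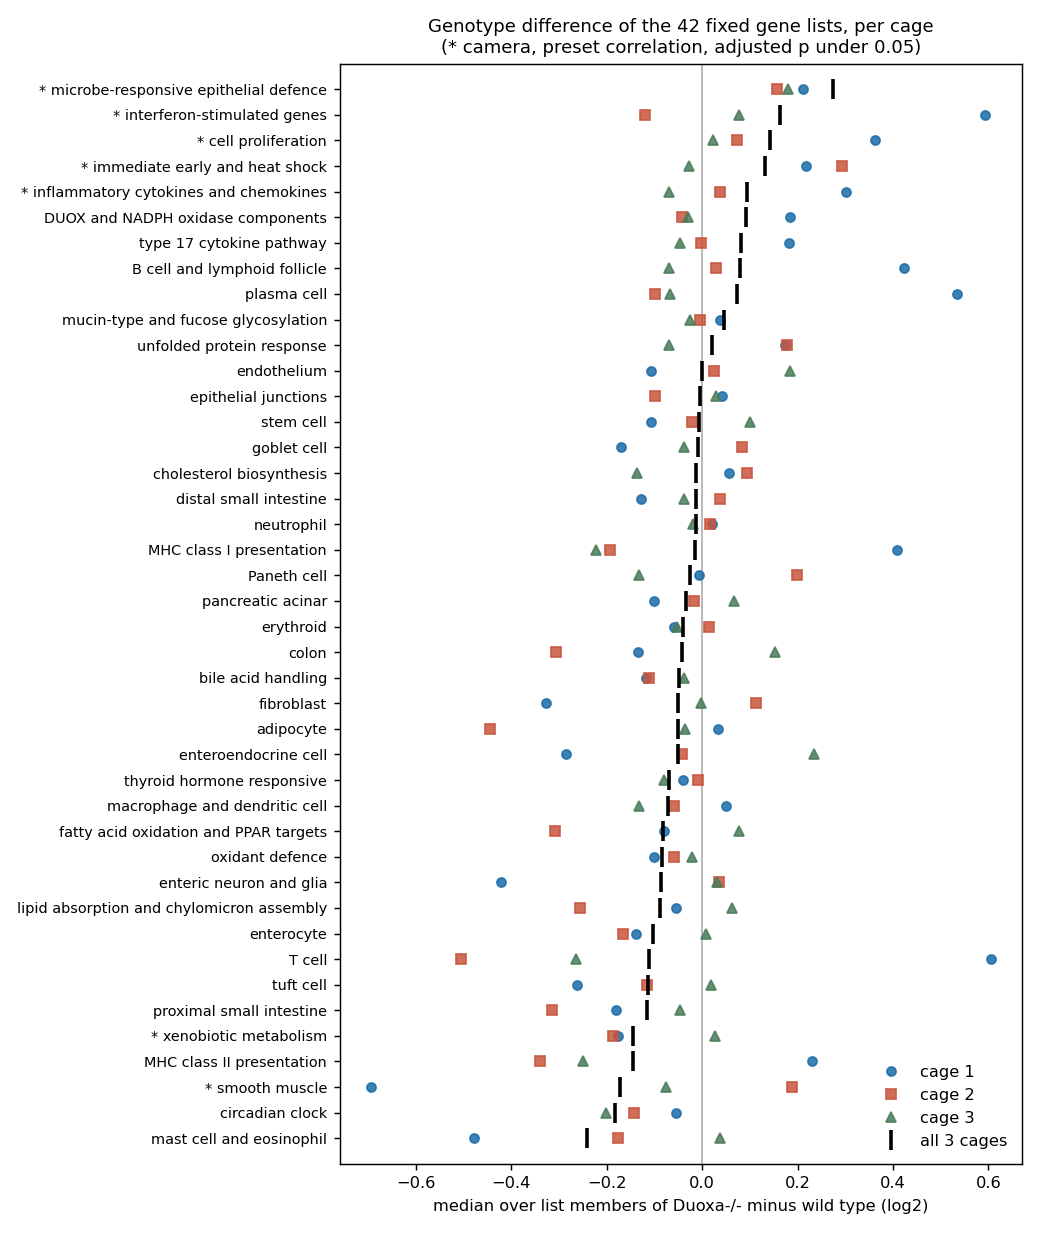
Median log2 difference, Duoxa-/- minus wild type, of the members of each of the 42 gene lists, with coloured points for the 3 cages, a black bar for the median of the members' means over the cages, and an asterisk for lists past camera's threshold at the preset correlation, which none passed with an estimated correlation. The defence list is above 0 in every cage, at 0.21, 0.16 and 0.18, while T cell genes stand at 0.61 in cage 1 and at -0.51 and -0.26 in cages 2 and 3.

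The lists called lower in Duoxa-/- pools by camera at the preset correlation, without the block, were xenobiotic metabolism and smooth muscle. Of the xenobiotic metabolism genes, 22 of 24 were lower, with a median of -0.14 and list medians of -0.18, -0.19 and 0.03 in cages 1, 2 and 3, among them the carboxylesterase Ces2a (-0.35, SE 0.17) and the cytochrome P450 genes Cyp2b10 (-0.21, SE 0.10) and Cyp3a13 (-0.16, SE 0.12). Smooth muscle genes had a median of -0.17, with 12 of 14 lower, among them Smtn (-0.45, SE 0.19), Des (-0.38, SE 0.22) and Flna (-0.31, SE 0.14), which encode proteins of the contractile and cytoskeletal apparatus. The smooth muscle list medians were -0.69 in cage 1, 0.19 in cage 2 and -0.08 in cage 3. Both lists passed camera (adjusted p = 0.043 for xenobiotic metabolism and 0.038 for smooth muscle), neither did with an estimated correlation (adjusted p = 0.909 for both), and in both 0 members passed over the list alone. The smooth muscle call ended without either pool of cage 1 (median -0.054, adjusted p = 0.844 without the wild-type and median -0.057, adjusted p = 0.552 without the Duoxa-/- pool), the median turning to 0.04 without that cage, or without the wild-type pool of cage 3 (adjusted p = 0.058). The smooth muscle median was -0.29 without the wild-type pool of cage 2, still called. The xenobiotic call ended without either pool of cage 1 (adjusted p = 0.299 and 0.091), the Duoxa-/- pool of cage 2 (median -0.053, adjusted p = 0.852) or the wild-type pool of cage 3 (adjusted p = 0.369). Without the Duoxa-/- pool of cage 3 its median was -0.27, still called. The xenobiotic call also ended with the mean of all probe sets of a gene (median -0.15, adjusted p = 0.053) and without cross-hybridising probe sets (median -0.13, adjusted p = 0.058).

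With cage as a block, 8 lists rather than 2 were lower by camera at the preset correlation, and the 6 added lists were mostly of absorptive function and of rarer mucosal cells. Mast cell and eosinophil genes had a median of -0.24 (blocked adjusted p = 0.0022), with Hdc (-0.27), Kit (-0.28) and Epx (-0.13) as the members of smallest p. Tuft cell genes had a median of -0.11 (blocked adjusted p = 0.0063), and Trpm5, the cation channel of tuft cell chemosensing, passed over the list alone only with the block (-0.42, adjusted p = 0.038, against 0.567 without it). Enterocyte genes had a median of -0.10 (blocked adjusted p = 0.0096), among them the sugar transporter Slc2a2 (-0.65), the trehalase Treh (-0.64) and the aminopeptidase Anpep (-0.36). Genes of the proximal small intestine (-0.12, blocked adjusted p = 0.025), of fatty acid oxidation (-0.08, blocked adjusted p = 0.028), with Pdk4 at -0.42 and Hadha at -0.35, and of the circadian clock (-0.18, blocked adjusted p = 0.045), with Nr1d1 at -0.23 and Cry1 at 0.36, were the others. The clock list mixes genes of opposite phases, so a single direction for it is hard to read. Of its 15 members, 8 were lower in all 3 cages and 3, Arntl, Clock and Cry1, higher in all 3. In cage 3 the list medians were 0.04 for mast cells and eosinophils, 0.02 for tuft cells, 0.01 for enterocytes and 0.08 for fatty acid oxidation. They were -0.05 there for the proximal small intestine and -0.20 for the clock. None of these 6 passed in the main fit without the block (adjusted p from 0.060 to 0.338), and none passed with the block and an estimated correlation (adjusted p = 0.862). Some alternatives without the block called some of them at the preset correlation, such as enterocytes with array weights (median -0.11, adjusted p = 0.021). Fatty acid oxidation was called without the Duoxa-/- pool of cage 3 (median -0.20, adjusted p = 1.9e-06). Tuft cells were called without the wild-type pool of cage 3 (median -0.23, adjusted p = 0.0037).

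Among 29 further lists, which passed in neither fit, median differences lay between -0.15 and 0.09. Genes of antigen presentation and lymphocytes were split by cage. MHC class II genes had a median of -0.15, T cell genes of -0.11 and MHC class I genes of -0.02. In cage 1 these medians were 0.23, 0.61 and 0.41, and without cage 1 they were -0.33, -0.36 and -0.23. All 3 passed camera without cage 1 at the preset correlation (adjusted p = 1.2e-04, 2.5e-10 and 0.0025), and an estimated correlation was not tested in that subset. Leaving out that cage took away the values of the opposite sign, so these calls do not speak for a genotype difference over the 3 cages. Cd74, the class II invariant chain, was lower in all 3 cages by a mean log2 difference of -0.53 and passed over the list alone only with the block (adjusted p = 0.027, against 0.640 without it). B cell and follicle genes (0.08) and plasma cell genes (0.07) had medians above 0, with Ms4a1 at 0.37 and Ighm at 0.21, although 3 of the 11 Ighm probe sets shared that sign. In cage 3 the medians of both lists were -0.07. Without the Duoxa-/- pool of that cage they were 0.16 and 0.18, both called by camera at the preset correlation (adjusted p = 0.023 and 0.0097). Macrophage and dendritic cell genes had a median of -0.07 and neutrophil genes of -0.01, with the dim calprotectin genes S100a8 and S100a9 at 0.59 and 0.63. Type 17 cytokine pathway genes had a median of 0.08, with Ccl20 at 0.62 and Ccr6, which encodes its receptor, at 0.32.

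Of the DUOX and NADPH oxidase components (median 0.09, mean -0.18), 2 members passed when adjusted over the list alone. They were Duoxa2 (adjusted p = 0.0013) and Nox4, a constitutively active NADPH oxidase, at -0.36 (adjusted p = 0.030). Duoxa2, a gene of the targeted locus, held the smallest p of this list, which eases the adjustment of Nox4. The list was not adjusted without Duoxa2, so that the Nox4 value does not stand on its own. Oxidant defence genes had a median of -0.08, with Hmox1, which encodes heme oxygenase, at -0.22, and the unfolded protein response had a median of 0.02, with Pdia6 at 0.25. Mucin-type and fucose glycosylation had a median of 0.05, with Galnt3 at 0.30, C1galt1 at 0.28 and Fut1 at -0.28, and only Fut2 passed over this list, with the block (adjusted p = 0.039, against 0.634 without it). Thyroid hormone responsive genes had a median of -0.07, and Slc16a10, a transporter of aromatic amino acids and thyroid hormones, at -0.39 passed over the list alone only with the block (adjusted p = 0.047, against 0.140 without it). Lipid absorption genes had a median of -0.09, with the cholesterol transporter Npc1l1 at -0.27, bile acid handling of -0.05, cholesterol biosynthesis of -0.01 and epithelial junctions of -0.01.

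Among the remaining cell type lists, medians were -0.01 for goblet cells, -0.03 for Paneth cells, -0.01 for stem cells and -0.05 for enteroendocrine cells, in which the somatostatin gene Sst stood at -0.33. Distal small intestine genes had a median of -0.01 and colon genes of -0.04. Without the Duoxa-/- pool of cage 3 the enteroendocrine median was -0.20 and the colon median -0.14. Both were called there by camera at the preset correlation (adjusted p = 7.8e-06 and 0.0015). Medians of the stromal and other lists were -0.05 for fibroblasts, -0.00021 for endothelium, -0.09 for enteric neurons and glia, -0.03 for pancreatic acinar cells, -0.04 for erythroid cells and -0.05 for adipocytes. Of the adipocyte list Pnpla2, the adipose triglyceride lipase, passed over the list alone (-0.42, adjusted p = 0.041). With the block the lipase Lipe passed too (-0.33, adjusted p = 0.047, against 0.077 without it). Without the block, members passed over the list alone in 2 of the 42 lists, adipocytes and the list holding Duoxa2. With the block, members passed in 7 lists. No adjustment was made over the 42 lists, so some lists are expected to hold such a member by chance. In 5 lists (neutrophil, endothelium, stem cell, Paneth cell, and DUOX and NADPH oxidase components) the median and the direction of camera differed in sign, and in the stem cell and Paneth cell lists the mean did too.

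The genotype difference of one cage had little in common with that of another. Across genes, which are not independent replicates, the differences of cages 1 and 2 correlated with r = 0.089, those of cages 1 and 3 with r = 0.0070 and those of cages 2 and 3 with r = 0.068. The spread of the differences was widest in cage 1 (SD 0.27, 106 genes over 2-fold), followed by cage 2 (SD 0.23, 54 genes) and cage 3 (SD 0.16, 13 genes). The sign was shared by all 3 cages in 5484 genes, 30.1% of those tested against 25% by chance, and all 5 genes with a mean difference over 2-fold were among them.

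The cages themselves differed in 2 genes at an adjusted p of 0.043 (limma F-test with genotype in the fit, 1130 genes at an unadjusted p under 0.05). Nebl, which encodes the actin-binding protein nebulette, had means of 7.67, 8.30 and 6.59 in cages 1, 2 and 3, a range of 3.25-fold. The kappa segment Igkv15-103 had means of 9.31, 10.37 and 8.69, a range of 3.21-fold. Of the 8 genes that followed without passing, 6 were highest in cage 3 at adjusted p values of 0.202, among them Pck1, the gluconeogenic enzyme, at 10.40 against 9.32 and 8.77, and the glutathione transferase Gsta3 at 9.09 against 7.65 and 7.94. Nat8f5 (adjusted p = 0.072) was likewise highest there at 9.04, and Slc30a10 was lowest there, at 8.09 against 9.13 and 9.41. The count of 2 was 30 without the wild-type and 53 without the Duoxa-/- pool of cage 1, 22 without the wild-type pool of cage 3, and 0 without either pool of cage 2. It was also 0 with cyclic loess, without dim genes, with the mean of a gene's probe sets or without the genotype term, and 21 with an intensity trend and robust prior.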

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

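Chosen after the data were seen was 1 setting, the block combined with an estimated correlation; the others were planned. No gene passed under any normalization, probe set or variance setting with an adjusted p under 0.05 over all genes, or with one under 0.1 in the unblocked fit of all arrays, apart from Duoxa2 without the wild-type pool of cage 3 or without cage 3. At an unadjusted p under 0.01 there were 42 genes higher and 89 lower, against 182 by chance, a looser threshold by construction. Without cage 3, 1 gene was lower, and leaving out single arrays gave 0 to 0 higher and 0 to 1 lower. The Duoxa2 difference lay between -2.79 and -2.01 when single arrays were left out and passed over the locus genes under every setting. The replicate block (cages as pairs) changed no gene call, with 0 higher, 0 lower and Duoxa2 at -2.34, and left lists higher at 5, but gave 8 lists lower in place of 2.

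Lists called higher numbered 5. With an estimated correlation there were 0, by fry 0, and in the paired replicate block fit with an estimated correlation 0; the same 3 settings gave 0, 0 and 0 lists lower in place of 2. Leaving out dim genes gave 3 higher, leaving out cage 1 gave 2 and leaving out cage 3 gave 8; single arrays gave 2 to 9, with 3 without the wild-type pool of cage 1, 2 without the Duoxa-/- pool of cage 2 and 9 without that of cage 3. Lists lower were 7 with all probe sets, 1 without cross-hybridising probe sets, 5 with array weights and 12 without cage 3; single arrays gave 1 to 10, with 1 without the wild-type pool of cage 1 or the Duoxa-/- pool of cage 2, 3 without the Duoxa-/- pool of cage 1, 6 without the wild-type pool of cage 2 and 10 without the Duoxa-/- pool of cage 3. Without cage 1 the cytokine list turned to a median of -0.0025, the interferon list to -0.0023 and smooth muscle to 0.038, and without cage 2 the immediate early list to -0.00020. The causes were not tested, beyond fewer arrays or genes where these were left out.

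Genes between cages numbered 2. They were 0 without the genotype term, 0 with cyclic loess, 4 with centred arrays, 0 without dim genes, 1 over all probe sets, 0 with mean probe sets and 21 with a trend and robust prior. Leaving out cage 1 gave 63, cage 2 gave 0 and cage 3 gave 0, and single arrays gave 0 to 53. The share of genes with 1 sign in 3 cages, 30.1%, was 28.9% with centred arrays, 32.4% without dim genes and 31.2% with mean probe sets; variance settings and left-out arrays give no other value for it.

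Of 2680 values of the 151 other named genes under the alternatives, 0 passed and 34 had the opposite sign. Of 879 values of lists, 79 had the opposite sign without a call in either setting. Duox1, at 4.75 in wild-type pools, is dim, and differences of dim genes are compressed.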

Other observations

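Tests of the interferon, proliferation, defence and clock patterns were chosen after those results had been seen, and the comparison of lists between cages was added then too; the counts of splits and the test of genes near the locus were set beforehand. Of genes outside the naming rule, chosen after their values were seen, Dmp1 and Il1rn had the smallest p of genes higher in Duoxa-/- pools besides Ifi27l2a. Il1rn, the interleukin-1 receptor antagonist, read 6.59 ± 0.05 in wild-type and 7.21 ± 0.15 in Duoxa-/- pools (SD, n = 3), with differences of 0.58, 0.80 and 0.46 in the 3 cages and all 3 of its probe sets higher. Dmp1, a matrix phosphoprotein, differed by 1.33 (SE 0.20) from a dim level of 4.62 in wild-type pools. Neither passed over all genes (limma adjusted p = 0.760).

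Of 126 tests of a gene list in 1 cage against the other cages, with genotype in the fit, 42 passed camera at the preset correlation. Xenobiotic metabolism genes stood at -0.24 in cage 2 and 0.34 in cage 3 against the other cages, proliferation genes at 0.24 in cage 2, and macrophage and dendritic cell genes at -0.24 in cage 3. Defence genes stood at 0.34 in cage 2 and -0.28 in cage 3, and tuft cell genes at 0.28 in cage 1 and -0.34 in cage 3. None of the 126 passed with an estimated correlation (smallest adjusted p = 0.712).

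Of the 10 splits of the 6 arrays into 3 and 3, which are too few for a share under 0.05, 9 gave at least the 7 lists of the real one. Any split reaches the real count of 0 genes, so that comparison cannot decide anything. Other splits gave at most 58 genes and at most 25 lists. The split with 58 genes set the wild-type pool of cage 1 and both pools of cage 3 against the rest, which points to a structure of the samples other than genotype. The real split parts the pools of all 3 cages, and the other 3 splits that do so gave 16, 8 and 14 lists and 0 genes each; the remaining 6 keep the pools of 1 or more cages on one side.

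The higher interferon and proliferation genes in Duoxa-/- pools may reflect the wild-type pool of cage 1 and what tissue it held. Without that array the interferon median was 0.021 and no longer called, and the proliferation median was 0.071 and called at the preset correlation (adjusted p = 0.014), an estimated one giving 0.909 on all arrays and not tested on this subset; without cage 1 it was 0.049 and not called, which leaves that pool open as its source. Over the 6 arrays, taken as exchangeable although cages pair them, the interferon score and the mean of the T and B cell scores had Pearson r = 0.88 (permutation p = 0.022, adjusted over 3 relations 0.067) and Spearman rho = 0.77 (permutation p = 0.10), and r = 0.57 without the 2 farthest arrays, and for proliferation r was 0.67 (permutation p = 0.15; rho = 0.49, permutation p = 0.36) and 0.24 without those arrays, with 0.999 and 0.968 over the differences within the 3 cages, too few pairs for a test. The T and B cell score itself differed between genotypes by 0.0041 (SD 0.41 over 3 cages) and the interferon score by 0.20, so these relations describe the spread between pools. In a linear model of the array scores, adjustment for the T and B cell score moved the interferon difference from 0.20 to 0.19. Its 95% interval was 0.02 to 0.37, and 0.0090 to 0.38 with the block. The proliferation difference stayed at 0.15 (95% interval -0.15 to 0.45). A linear effect of this score thus took up little of either mean difference in the 6 arrays. Without the wild-type pool of cage 1 the interferon difference moved from 0.03 to 0.18 (95% interval -0.19 to 0.56). Lymphocyte content beyond this score and an effect of genotype both stay open.

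The higher defence genes in Duoxa-/- pools were not set by 1 cage alone, since the lowest median with 1 cage left out was 0.18. Single arrays moved the median further, to 0.15 and no longer called without the Duoxa-/- pool of cage 2 and to 0.50 without that of cage 3. RNA degradation of one pool stays open. In cages 1 and 3 the pools differed by under 0.2 in the 3' minus 5' value of beta-actin, a limit set after the results were seen. The list medians there were 0.21 and 0.18. The list means were 0.35 (SE over members 0.19) and 0.16 (SE 0.16), an SE that measures the spread between genes and not between pools. The same value of the GAPDH control was 0.20 and 0.17 in the wild-type and Duoxa-/- pools of cage 1, and -0.08 and -0.06 in cage 3. In cage 2, where it was 0.43 and 0.03, the list median was 0.16 and the mean 0.39. The list was thus higher in 2 cages whose pools were close in both controls. With 1 pair of pools per cage there is no spread to set this against. Lymphocyte content remains open, with r = 0.27 against the T and B cell scores (permutation p = 0.63; rho = 0.31, permutation p = 0.56; r = -0.053 without the 2 farthest arrays; r = 0.21 within the 3 cages). The T and B cell score differed by 0.48, -0.29 and -0.18 in cages 1, 2 and 3 and the defence score by 0.35, 0.39 and 0.16, which goes against it in cages 2 and 3. At equal T and B cell score the defence difference stayed at 0.30, so a linear effect of this score took up little of it in the 6 arrays. Its 95% interval was -0.68 to 1.27, and without the wild-type pool of cage 1 adjustment moved the difference from 0.27 to 0.43. The list did not pass with an estimated correlation, and an effect of genotype is open as well.

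Median values of clock output genes and of genes of the opposite phase moved in opposite directions in cage 3 against the other cages, in both genotypes. Pools taken at another time of day are a candidate explanation. Between genotypes, the opposite-phase genes Arntl, Clock and Cry1 were higher in the Duoxa-/- pool of every cage, while 8 of the 15 clock list members were lower in every cage. This genotype difference was not tested by phase. No single clock gene passed the F-test between cages. The clock list in cage 3 passed camera at the preset correlation (adjusted p = 1.0e-04), and not with an estimated one (adjusted p = 0.712). Clock output genes stood at a median of 0.47 in cage 3 against the others and genes of the opposite phase at -0.42, with Dbp at 0.73, Tef at 0.54, Npas2 at -0.91 and Arntl at -0.64, while the output gene Nr1d1 stood at -0.17, Bhlhe41 at 0.05 and the opposite-phase gene Cry1 at 0.17. Values of 4 of the 14 genes (Hlf, Per3, Nr1d1 and Cry1) had been seen beforehand and over all 14 the 2 arms differed by 0.89; over the other 10 the 2 arms differed by 1.03 (exact permutation of the arm labels, two-sided p = 0.033; genes are not independent). Sampling times were not analysed here, and a litter difference unrelated to time was not tested.

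A chromosome segment that came with the targeted allele could alter genes near the locus. The 40 measured genes nearest to it had a median absolute t at the 73.2 percentile of windows of 40 neighbours, with 4 at an unadjusted p under 0.05 where 2 are expected, the smallest for Bambi-ps1, which leaves this open. Bambi itself, chosen after its values were seen, differed by 0.04 (SE 0.10).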
